A study of Mus musculus with 8 samples.

How the data were processed

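Total RNA was taken from splenic regulatory T cells (Tregs, CD4 T cells that hold back immune responses) of mice without tumors, and libraries were made with the SMART-Seq v4 low-input kit, per the labels. The 8 libraries form 4 groups of 2, named from the genotype, sort and strain in the labels. The groups are YFP+ Tregs of a C57BL/6 control (WT YFP+, numbers 23 and 24), YFP+ and YFP- Tregs of SRC-3 knockout mice on a mixed C57BL/6 and 129SvEv background (KO YFP+ and KO YFP-, numbers 84 and 85 in each) and Tregs of a second control on a 129SvEv background, named SRC-3ff in its title and with no YFP sort in its label (SRC-3ff, numbers 68 and 72). The labels do not say what YFP marks or which part of the gene is deleted. Strain therefore differs between each control and the knockout, and the sort differs between SRC-3ff and both YFP+ groups.

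The deposited table holds FPKM (fragments per kilobase of transcript, scaled to the mapped fragments) for 55487 genes and 8 libraries, made by the authors. Per the submitters' processing notes, Trim Galore, STAR and StringTie were used with the mm10 (GRCm38) mouse genome. Their versions, the annotation and the use of strand in counting are not given in the sources used here. FPKM are not counts, and steps of whole reads are not kept by StringTie's estimates, so the depth of each library is unknown and no counting interval was computed. The 13 mitochondrially encoded genes are listed at 0 in all 8 libraries, so a value of 0 in this table can be a missing estimate rather than a missing transcript. Genes listed at 0 in a library are given per library, with no fold against a group at 0. Of the gene identifiers, 55227 matched GENCODE M21 on GRCm38, which gave the coordinates, and 260 did not. Of the symbols, 114 occur more than 1 time, and each keeps its plain name for the identifier with the highest mean.

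FPKM were used as deposited, without further scaling. The test was limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a trend) on log2(FPKM + 1), so a fold change is on that scale and understates the change of low genes. Genes with at least 1 FPKM in at least 2 libraries were tested, 14134 in all. One model with the 4 groups was fitted to the 8 libraries, which leaves 4 residual degrees of freedom, and 6 comparisons were taken from it. P-values were adjusted over genes within each comparison by the Benjamini-Hochberg method with a threshold of 0.05, and the error given with a log2 fold change is limma's standard error. An exact permutation test of 2 libraries against 2 cannot give a two-sided p below 0.333, so the calls rest on the spread shared across genes and groups. Separate animals are not stated for all libraries, so these p-values measure the spread between the libraries, which may be technical. Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 was used for tables and plots.

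Before the data were examined, the groups, the test, the comparisons, 36 gene lists, the alternatives and the rule for named genes were fixed. Lists with at least 5 tested members, 32 of them, were tested with limma's camera at a preset correlation between genes of 0.01, then with an estimated correlation, and with limma's fry. Adjusted p-values of lists are over the 32 lists of a comparison. The rule named Ncoa3 and Foxp3 in every library first. It then took the 10 largest changes in each direction among genes past the threshold with a group mean of at least 5 FPKM and no overlap of libraries, leaving out predicted genes, clone names, pseudogenes and antigen receptor segments (3 in each direction for the KO YFP- comparisons with controls). From each list it took up to 4 members with the smallest p. Il2ra, Ikzf2, Ctla4, Tnfrsf18, Il10, Ifng, Cxcl9 and Cxcr3 were always included in the comparison of KO YFP+ with WT YFP+, and sex-linked and strain genes in every library. Values are given for only part of the genes the rule names, and the counts of named genes that held cover all of them. The values of 1 of these genes are not reported here. Other genes are said to have been chosen after their values were seen.

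The test was tested on simulated data, with 13640 genes tested in KO YFP+ against WT YFP+. Each gene had its mean over the 8 libraries in all groups, with independent normal noise at its residual spread. Changes were added in KO YFP+ only. Such noise follows the model, so correlation between genes and other departures from the model were not covered. Of 100 genes with a simulated log2 change of 1, 54% were recovered, and of 100 with a change of 2, 93% were recovered. The changed genes were all drawn from those with a mean above 5 FPKM, so recovery of lower genes was not measured. Of the 152 calls, 3.29% were genes with no simulated change. In the same simulated data WT YFP+ against SRC-3ff, between which no change was simulated, gave 0 calls.

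The alternatives were a pseudocount of 0.1, no filter on low values, a minimum of 5 FPKM, median-of-ratios scaling, quantile normalization, only the 4 libraries compared (2 residual degrees of freedom), robust empirical Bayes, the animal number as a block (3 residual degrees of freedom), an estimated correlation for lists, and each library left out in turn. A library left alone in its group was assumed to vary like the other groups. Leaving out the 444 tested immunoglobulin and T cell receptor segments was added after seeing the data. The numbers 84 and 85 occur in both knockout sorts and were read as the same 2 animals. Deviations of same-numbered libraries from their group means had a correlation of 0.137 across the 14134 genes, and of 0.122 across the 13690 genes that are not segments. Genes are not independent replicates. Across genes, libraries of 1 group had a Pearson r of 0.966 to 0.975, and libraries of different groups 0.880 to 0.966. The median log2 fold change of all tested genes lay between -0.025 and 0.033 in the 6 comparisons, and between -0.075 and 0.070 with quantile normalization.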

Results

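RNA sequencing compared splenic Tregs of SRC-3 knockout mice with Tregs of 2 control groups, to look for expression differences that bear on the anti-tumor effects of the knockout Tregs. SRC-3 is a transcriptional coactivator of nuclear receptors and other transcription factors, encoded by Ncoa3. The 8 libraries formed 4 groups of 2. The sum of FPKM per library ranged from 384107 (WT YFP+ 23) to 416393 (KO YFP+ 85), and 12573 to 13251 genes reached at least 1 FPKM. Immunoglobulin and T cell receptor segments took 2.73% and 3.34% of the FPKM sum in WT YFP+ and 2.94% and 2.96% in KO YFP+. They took 7.21% and 5.34% in KO YFP- and 4.86% and 9.38% in SRC-3ff. The depth of each library is unknown.

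Ncoa3 (ENSMUSG00000027678, chromosome 2, 165992636 to 166073242, GRCm38) was lowest in the YFP+ knockout cells. It measured 46.3 and 42.7 FPKM in WT YFP+ 23 and 24, 10.9 and 10.2 in KO YFP+ 84 and 85, 32.1 and 32.2 in KO YFP- 84 and 85, and 49.7 and 35.4 in SRC-3ff 68 and 72. The log2 fold change of KO YFP+ was -1.98 ± 0.16 against WT YFP+ (limma adjusted p = 0.0034), -1.52 ± 0.16 against KO YFP- (adjusted p = 0.0050) and -1.90 ± 0.16 against SRC-3ff (adjusted p = 0.0027). These 3 calls held with each library left out. Ncoa3 in KO YFP- did not pass against WT YFP+ (log2 fold change -0.46, adjusted p = 0.13) or SRC-3ff (-0.38, adjusted p = 0.27). A loss of Ncoa3 was therefore not shown in the libraries labelled KO YFP-, and that name follows the label only. The table gives a value per gene, so reads of a deleted exon cannot be told from those of the rest of the gene. Ncoa1 and Ncoa2, the paralogs that encode SRC-1 and SRC-2 and were chosen after their values were seen, passed in none of the 6 comparisons with limma.

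Foxp3 (ENSMUSG00000039521, chromosome X, 7573644 to 7595245), the transcription factor that defines Tregs, was low in both YFP+ groups and high in the groups without a YFP+ sort. It measured 31.0 and 19.9 FPKM in WT YFP+ 23 and 24 and 21.0 and 22.9 in KO YFP+ 84 and 85. It measured 161 and 113 in KO YFP- 84 and 85, and 205 and 151 in SRC-3ff 68 and 72. KO YFP+ and WT YFP+ did not differ past the threshold (log2 fold change -0.17 ± 0.26, limma adjusted p = 0.87), and the difference was 0.14 without WT YFP+ 23. Foxp3 was lower in KO YFP+ than in KO YFP- (-2.56 ± 0.26, adjusted p = 0.0047) and SRC-3ff (-2.95 ± 0.26, adjusted p = 0.0032), and lower in WT YFP+ than in SRC-3ff (-2.78 ± 0.26, adjusted p = 0.0018). Cd4 measured 195 ± 24.1 FPKM in WT YFP+, 174 ± 16.9 in KO YFP+, 154 ± 20.7 in KO YFP- and 156 ± 17.3 in SRC-3ff (SD, n = 2 each), and passed in none of the 6 comparisons. Cd4 was chosen after its values were seen.

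KO YFP+ against WT YFP+ compared the same sort between the SRC-3 knockout and a control that also differed in strain. Supt16, a subunit of the FACT histone chaperone, rose from 6.10 ± 0.476 FPKM in WT YFP+ to 42.9 ± 4.81 in KO YFP+ (SD, n = 2 each). Commd6, a COMM domain protein, rose from 10.8 ± 2.19 to 55.2 ± 5.43. Ifi206, a member of the interferon-inducible Ifi200 family, fell from 36.9 ± 2.60 to 2.58 ± 0.912, and Dcaf13, a protein of ribosome biogenesis, from 36.3 ± 2.38 to 5.54 ± 0.0983. Atp5e, the epsilon subunit of ATP synthase, fell from 165 ± 3.70 to 41.2 ± 0.278, and Ube2l3, a ubiquitin-conjugating enzyme, from 71.4 ± 22.9 to 12.2 ± 0.298. In KO YFP- and SRC-3ff these 6 genes lay near their KO YFP+ values, for example 41.1 and 49.3 FPKM for Supt16 and 4.71 and 5.15 for Dcaf13. Zmiz1, a PIAS-like transcriptional coactivator, fell from 10.2 and 9.83 in WT YFP+ 23 and 24 to 2.00 and 0.929 in KO YFP+ 84 and 85, against group means of 11.6 in KO YFP- and 10.2 in SRC-3ff. Asns, the asparagine synthetase, rose from 1.48 and 1.98 to 11.2 and 8.81 in the same libraries, Ada, the adenosine deaminase, from 5.54 ± 0.150 to 14.3 ± 2.69, and Ado, a thiol dioxygenase, from 5.33 ± 1.05 to 12.7 ± 0.316. Rbm45, an RNA-binding protein, rose by a log2 fold change of 3.21, and Dynlt1b, a dynein light chain, by 2.01. H2-Q2, a class Ib MHC gene, changed by -2.26, and Smarcd1, a subunit of the BAF remodelling complex, by -1.89. For Rbm45, Dynlt1b, H2-Q2 and Smarcd1 the mean of KO YFP- and SRC-3ff also lay near KO YFP+ (3.34, 1.74, -2.33 and -2.01 from WT YFP+, log2). For Asns and Ada that mean (1.32 and 0.68) lay nearer KO YFP+ (2.01 and 1.21) than WT YFP+. For Ado it lay nearer WT YFP+ (0.11, with KO YFP+ at 1.12).

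In all, 107 of 14134 genes passed with limma, 43 higher and 64 lower in KO YFP+, and 29 of them were immunoglobulin or T cell receptor segments. The 2 groups did not overlap in 5657 genes, where chance gives 33.3% of those tested. The count was 74 without WT YFP+ 23, 64 without WT YFP+ 24, 50 without KO YFP+ 84 and 44 without KO YFP+ 85, and 25 with only the 4 libraries compared. Of 25 named genes that passed, 8 held with each library left out, Supt16, Commd6, Ifi206, Dcaf13, Atp5e, Ube2l3, Ncoa3 and Fos. Of these, Commd6 and Ube2l3 did not pass with only the 4 libraries compared (adjusted p = 0.054 and 0.084), and the other 6 held in every alternative. In that setting Ifi206, Dcaf13, Atp5e, Ncoa3 and Fos passed only narrowly (limma adjusted p = 0.04997 for each). Zmiz1 did not pass without WT YFP+ 23 or without WT YFP+ 24 (adjusted p = 0.060 for each), without a filter on low values (0.063) or with only the 4 libraries compared (0.11). Asns, Ada and Ado did not pass without any 1 of WT YFP+ 23, WT YFP+ 24, KO YFP+ 84 and KO YFP+ 85 (adjusted p of 0.079 to 0.13, 0.078 to 0.16 and 0.066 to 0.21). Rbm45 ended without WT YFP+ 23, WT YFP+ 24 or KO YFP+ 84 (highest 0.12), Dynlt1b without WT YFP+ 23 or KO YFP+ 85 (highest 0.076), H2-Q2 without WT YFP+ 24 (0.064) and Smarcd1 without KO YFP+ 85 (0.058). Without a filter on low values Asns, Ada, Ado, Rbm45, Dynlt1b and H2-Q2 did not pass (adjusted p = 0.11, 0.12, 0.12, 0.15, 0.099 and 0.060). With only the 4 libraries compared none of these 6 did (0.095, 0.17, 0.20, 0.11, 0.11 and 0.11), nor did Smarcd1 (0.079). With the animal number as a block, Ado did not pass (adjusted p = 0.077).

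Calls were also counted in 3 regions that were chosen after the calls were seen, with no test of enrichment. Of 117 tested genes in the T cell receptor alpha variable region (chromosome 14, 52427928 to 53876752), 27 passed, which is 23.1% against 0.757% of all tested genes. In the MHC (chromosome 17, 33974659 to 37274484) 10 of 129 passed, and among the Ifi200 genes (chromosome 1, 173468485 to 173942672) 4 of 11. Reads of these families and of ribosomal protein genes can be split between near-identical copies, so single members are uncertain. Rps18 (log2 fold change 0.86, adjusted p = 0.031) and Rps3a1 (-0.83, adjusted p = 0.045), 2 ribosomal protein genes with many pseudogenes, passed in opposite directions. Neither passed without any 1 of WT YFP+ 23, WT YFP+ 24, KO YFP+ 84 and KO YFP+ 85 (highest adjusted p = 0.21 and 0.23), with the animal number as a block (0.070 and 0.091), without a filter on low values (0.14 and 0.17) or with only the 4 libraries compared (0.10 and 0.22). Rps18 also did not pass with quantile normalization (0.091).

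Of the Treg genes named beforehand, none passed with limma in KO YFP+ against WT YFP+. Il2ra, the IL-2 receptor alpha chain, measured 94.0 ± 2.33 against 113 ± 0.129 FPKM (adjusted p = 0.54), Ctla4, the checkpoint receptor, 66.8 ± 2.17 against 71.9 ± 4.09 (0.91), and Tnfrsf18, which encodes GITR, 219 ± 23.3 against 185 ± 14.7 (0.64). Ikzf2, which encodes Helios, measured 27.2 ± 1.86 against 16.7 ± 3.64 (0.39) and Cxcr3, a chemokine receptor of Th1-type cells, 35.4 ± 2.31 against 32.0 ± 0.818 (0.78). The cytokine genes Il10 (0.481 ± 0.195 against 0.215 ± 0.252) and Ifng (0.798 ± 0.0888 against 0.832 ± 0.0442) were below 1 FPKM in both groups, and the Ifng difference of -0.03 was 0.023 without KO YFP+ 85. Cxcl9, an interferon-induced chemokine, was listed at 0.0105 and 0.0186 in WT YFP+ and at 0 in both KO YFP+ libraries, and was not tested. At an unadjusted p below 0.05, 1476 genes differed in this comparison.

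**Figure D1:**
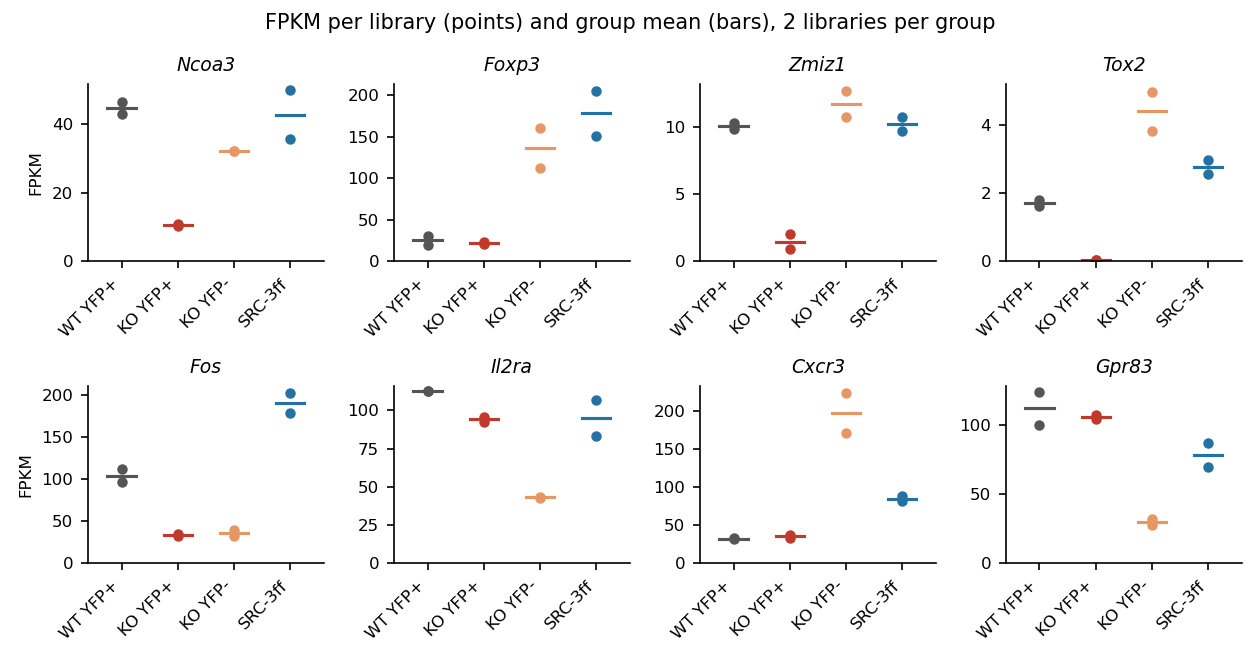
FPKM in each of the 8 libraries (points) with group means (bars) for Ncoa3, Foxp3, Zmiz1, Tox2, Fos, Il2ra, Cxcr3 and Gpr83, with 2 libraries per group. Ncoa3 measured 10.9 and 10.2 FPKM in KO YFP+ and at least 32.1 in each other library, while Foxp3 was at most 31.0 in the 4 YFP+ libraries and at least 113 in the other 4.

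Of 26 measured immediate early genes, which respond within minutes to stimulation of a cell, 3 were lower in KO YFP+ than in WT YFP+, 0 were higher and 23 did not pass, and 9 were lower when adjusted over the list alone. Fos, a subunit of AP-1, fell from 104 ± 10.7 to 34.1 ± 1.60 FPKM (log2 fold change -1.58 ± 0.13, adjusted p = 0.0039), and Junb, another AP-1 subunit, from 620 ± 13.5 to 375 ± 8.33 (adjusted p = 0.042). Ppp1r15a, a stress-induced regulator of eIF2 alpha phosphatase, fell from 84.5 ± 0.679 to 44.2 ± 0.697 (adjusted p = 0.0092). The list had a median log2 fold change of -0.23 and passed with camera (adjusted p = 1.5e-07), but not with an estimated correlation (adjusted p = 0.29 with an estimated correlation) or with fry (adjusted p = 0.060). The Fos call held with each library left out. Junb and Ppp1r15a did not pass without any 1 of WT YFP+ 23, WT YFP+ 24, KO YFP+ 84 and KO YFP+ 85 (highest adjusted p = 0.24 and 0.085) or with only the 4 libraries compared (0.15 and 0.078). Junb also did not pass with the animal number as a block (0.061), without a filter on low values (0.16) or with quantile normalization (0.051). In KO YFP+ against KO YFP- the list did not pass (1 higher and 1 lower, median 0.07, camera adjusted p = 0.28). Nor did Fos (log2 fold change -0.07, limma adjusted p = 0.85), Junb (0.30, adjusted p = 0.20) or Ppp1r15a (0.29, adjusted p = 0.15). A difference from KO YFP-, in which a loss of Ncoa3 was not shown, was therefore not seen for these 3 genes.

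Another 4 of the 32 lists passed with camera in this comparison, and none did with an estimated correlation (adjusted p = 0.93 with an estimated correlation for each). With an estimated correlation 0 of the 32 lists passed with camera, 1 at an unadjusted p below 0.05, and 0 passed with fry. Oxidative phosphorylation genes had a median of 0.15 (adjusted p = 0.0010), while the 1 of 42 members that passed, Atp5e, was lower (also 1 when adjusted over the list alone). Genes of resting lymphocytes had a median of -0.20 (adjusted p = 0.0016), with 0 of 17 members past the threshold and 2 lower when adjusted over the list alone. Interferon gamma response genes (median 0.13, adjusted p = 0.016) and cholesterol synthesis genes (median -0.15, adjusted p = 0.040) had 0 of 27 and 0 of 25 members past the threshold, also 0 when adjusted over the list alone. Both lost the call with quantile normalization (adjusted p = 0.066). Without WT YFP+ 23 the oxidative phosphorylation and cholesterol lists did not pass (adjusted p = 0.13 and 0.36), and without KO YFP+ 85 the former did not (0.062). Without WT YFP+ 24 or KO YFP+ 84 the interferon gamma list did not pass (0.48 and 0.26), nor did the cholesterol list without KO YFP+ 84 (0.19). The Treg identity list (19 measured, median 0.10, adjusted p = 0.68) and the effector Treg list (25 measured, median 0.11, adjusted p = 0.40) had 0 members past the threshold, with 2 lower and 0 when adjusted over the list alone.

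**Figure D2:**
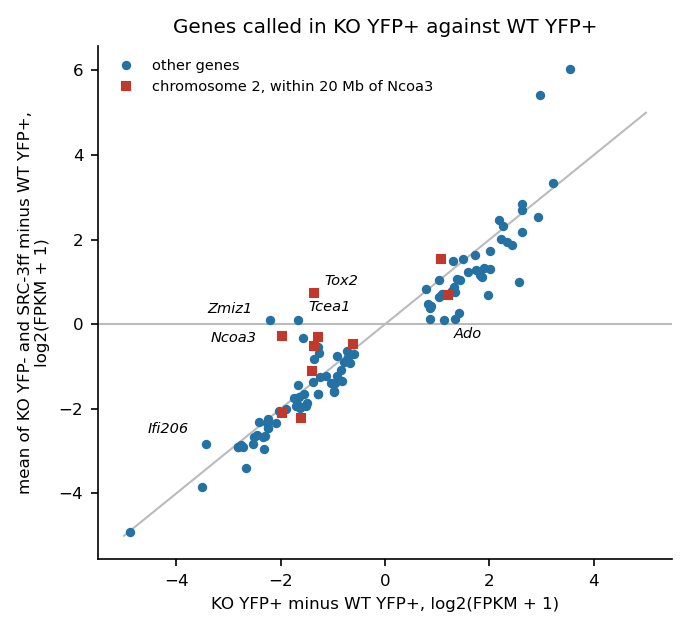
Each point is 1 of the 107 genes that differed between KO YFP+ and WT YFP+, with that log2 difference on the x axis and the mean of KO YFP- and SRC-3ff minus WT YFP+ on the y axis (log2). On the grey diagonal the other 4 libraries equal KO YFP+, on the grey horizontal line they equal WT YFP+, and red squares lie on chromosome 2 within 20 Mb of Ncoa3. For 91 of the 107 genes the other libraries lay nearer KO YFP+.

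KO YFP+ against KO YFP- compared the 2 sorts of the same 2 animals. Klf2, a transcription factor of quiescence, was higher in KO YFP+ and measured 228 ± 9.23 FPKM against 136 ± 0.569 (log2 fold change 0.74 ± 0.08, limma adjusted p = 0.0054). Ccr7, the lymph node homing receptor, was also higher (1.58 ± 0.14, adjusted p = 0.0038). Gpr83, a receptor gene enriched in Tregs, measured 106 ± 2.37 against 29.7 ± 2.95, and Gata1, a transcription factor, 19.2 ± 1.41 against 4.80 ± 0.162. Lower in KO YFP+ were Cxcr6, a chemokine receptor of effector cells (5.31 ± 1.46 against 355 ± 144, log2 fold change -5.78 ± 0.37, adjusted p = 0.0024), and Ccl5, a chemokine of effector and NK cells (5.56 ± 1.31 against 88.7 ± 0.301). Klrk1, which encodes NKG2D, measured 0.0537 ± 0.0421 against 37.5 ± 16.7, Tbx21, which encodes T-bet, 4.74 ± 0.498 against 59.1 ± 24.2, and Lgals3, which encodes galectin-3, 6.53 ± 1.71 against 184 ± 3.45. Each of these genes passed and held with each library left out. Il2ra was higher (94.0 against 43.1 FPKM, log2 fold change 1.11, adjusted p = 0.0060), but not without KO YFP+ 84 (adjusted p = 0.053).

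Of 14134 genes, 693 passed, 204 higher and 489 lower in KO YFP+ (239 and 383 with quantile normalization), and 95 of them were segments. The groups did not overlap in 49.0% of genes (33.3% by chance). Of 75 named genes that passed, 30 held with each library left out. The count was 156 without KO YFP+ 84, 140 without KO YFP+ 85, 345 without KO YFP- 84, 238 without KO YFP- 85 and 226 without a filter on low values. Among the lists, 14 of 25 effector Treg genes fell and 1 rose (21 and 1 when adjusted over the list alone, median -1.27, camera adjusted p = 5.4e-15, adjusted p = 0.092 with an estimated correlation). In the list were Cxcr3 (35.4 ± 2.31 against 197 ± 36.8) and S100a6, a calcium-binding protein (41.8 ± 9.01 against 265 ± 1.08), whose call was lost without a filter on low values (adjusted p = 0.055). Of 17 resting lymphocyte genes, 7 rose and 2 fell (10 and 2 when adjusted over the list alone, median 0.74, camera adjusted p = 5.8e-06, adjusted p = 0.15 with an estimated correlation). Of 19 Treg identity genes, 4 rose and 1, Foxp3, fell (5 and 4 when adjusted over the list alone), and the list did not pass (median 0.12, adjusted p = 0.22).

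Of 12 NK cell markers 10 were lower in KO YFP+ (11 when adjusted over the list alone, median -2.25, camera adjusted p = 9.6e-14, adjusted p = 0.090 with an estimated correlation). Of 16 B cell markers 5 were lower (13 when adjusted over the list alone, median -1.48, camera adjusted p = 1.3e-09, adjusted p = 0.21 with an estimated correlation). Of 12 plasma cell markers 3 were lower (7 when adjusted over the list alone, median -2.82, camera adjusted p = 1.0e-06, adjusted p = 0.30 with an estimated correlation). Sdc1, the plasma cell surface protein syndecan-1, measured 0.253 ± 0.290 FPKM in KO YFP+ against 12.2 ± 2.15 in KO YFP- and 22.4 ± 9.26 in SRC-3ff, and H2-Ab1, an MHC class II gene of B cells, 2.39 ± 0.319 against 31.8 ± 10.2 and 84.8 ± 29.6. The H2-Ab1 call against KO YFP- was lost without KO YFP+ 84, KO YFP+ 85 or KO YFP- 84 (highest adjusted p = 0.085), and without a filter on low values (0.083). Ribosomal protein genes were higher in KO YFP+, 8 of 71 (37 when adjusted over the list alone, median 0.40, camera adjusted p = 6.2e-17, adjusted p = 0.21 with an estimated correlation), a direction kept with median-of-ratios scaling and with quantile normalization. Of the 32 lists, 18 passed with camera, 16 with fry and 0 with camera and an estimated correlation, where 9 had an unadjusted p below 0.05 and the smallest adjusted p was 0.090.

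KO YFP+ against SRC-3ff compared the knockout cells with the second control, with strain and sort also differing. Foxp1, a transcription factor of quiescent T cells, was higher in KO YFP+ (73.5 ± 4.95 against 19.9 ± 4.41 FPKM, log2 fold change 1.85 ± 0.15, limma adjusted p = 0.0021), as was Isg15, an interferon-induced ubiquitin-like protein (log2 fold change 1.54 ± 0.17, adjusted p = 0.0059). Fos was lower (34.1 ± 1.60 against 191 ± 16.9, log2 fold change -2.45 ± 0.13, adjusted p = 0.00097), and so were Cxcr6 (5.31 against 224 FPKM), Lgals3 (6.53 against 227) and Gzmb, which encodes granzyme B (0.720 ± 0.350 against 9.87 ± 1.85). Each of these calls held with each library left out. Rpl34, a ribosomal protein gene, measured 76.3 ± 0.733 against 8.35 ± 1.91, and was 95.4 ± 37.0 in WT YFP+ and 63.1 ± 0.188 in KO YFP-. Its many pseudogenes leave its value uncertain.

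Of 14134 genes, 1448 passed, 587 higher and 861 lower in KO YFP+ (689 and 705 with quantile normalization), with 128 segments, and 61.0% of genes did not overlap (33.3% by chance). Of 98 named genes that passed, 34 held with each library left out. The count was 310 without KO YFP+ 84, 215 without KO YFP+ 85, 229 without SRC-3ff 72 and 1061 without SRC-3ff 68. It was 567 without a filter on low values and 537 with only the 4 libraries compared. Of 28 interferon response genes 9 rose and 0 fell (16 and 0 when adjusted over the list alone, median 0.79, camera adjusted p = 1.8e-08, adjusted p = 0.32 with an estimated correlation). Of 26 immediate early genes 9 fell (9 lower and 1 higher when adjusted over the list alone, median -0.42, camera adjusted p = 0.0041, adjusted p = 0.27 with an estimated correlation). Of 25 effector Treg genes 13 fell (17 when adjusted over the list alone, median -1.08, camera adjusted p = 1.2e-09, adjusted p = 0.27 with an estimated correlation). Of 32 cell cycle genes 1 fell, Top2a, which encodes a DNA topoisomerase (18 when adjusted over the list alone, median -0.74, camera adjusted p = 3.0e-07, adjusted p = 0.46 with an estimated correlation). Top2a did not pass without KO YFP+ 84, KO YFP+ 85 or SRC-3ff 72 (highest adjusted p = 0.11), or without a filter on low values (0.066). Of 12 NK cell and 16 B cell markers, 8 and 6 were lower (11 and 12 when adjusted over the list alone, camera adjusted p = 4.8e-08 and 2.1e-08, adjusted p = 0.27 and 0.29 with an estimated correlation). The Treg identity list had 1 member higher and 2 lower (2 and 3 when adjusted over the list alone), with a median of 0.14, a mean of -0.04, the test's direction up and an adjusted p of 0.52.

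Genes that differed from both controls in 1 direction numbered 19, 9 higher and 10 lower in KO YFP+. Independent lists of the same sizes would share 5.68 genes (1.79 higher and 3.90 lower). The KO YFP+ libraries, 2 in number, could not be split, so part of the excess may come from those shared libraries. Of the 19, 7 also differed from KO YFP- in the same direction, which were Ncoa3, Zmiz1, Tcea1 and Tox2 (lower) and Ado, H2-DMa and the predicted gene Gm4349 (higher). Tcea1, the elongation factor TFIIS, measured 3.98 FPKM in KO YFP+ against 14.8 in WT YFP+, 15.2 in KO YFP- and 16.9 in SRC-3ff (log2 fold change -1.67 against WT YFP+, adjusted p = 0.0019). Tox2, an HMG-box transcription factor encoded within 20 Mb of Ncoa3 on chromosome 2, measured 0.0507 against 1.72, 4.42 and 2.77 (-1.37, adjusted p = 0.029), and H2-DMa, an MHC class II peptide exchange chain, 55.5 against 30.1, 33.8 and 32.3 (0.86, adjusted p = 0.016). Tcea1, Tox2, H2-DMa and Gm4349 were chosen after their values were seen. The Tcea1 calls held with each library left out, but the call against WT YFP+ was lost with only the 4 libraries compared (adjusted p = 0.078). Tox2, H2-DMa, Ado and Gm4349 did not pass against WT YFP+ without any 1 of WT YFP+ 23, WT YFP+ 24, KO YFP+ 84 and KO YFP+ 85 (highest adjusted p = 0.17, 0.14, 0.21 and 0.19). Against SRC-3ff, Ado did not pass without any 1 of KO YFP+ 84, KO YFP+ 85, SRC-3ff 68 and SRC-3ff 72 (highest 0.087), nor H2-DMa and Gm4349 without KO YFP+ 84, KO YFP+ 85 or SRC-3ff 72 (highest 0.066 and 0.070). Against KO YFP-, Ado and Gm4349 did not pass without any 1 of KO YFP+ 84, KO YFP+ 85, KO YFP- 84 and KO YFP- 85 (highest 0.12 and 0.13), nor H2-DMa without KO YFP+ 84, KO YFP+ 85 or KO YFP- 85 (highest 0.092). With the animal number as a block, Tox2, Ado and Gm4349 did not pass against WT YFP+ (adjusted p = 0.052, 0.077 and 0.056). With only the 4 libraries compared, Tox2, H2-DMa, Ado and Gm4349 did not pass against WT YFP+ (0.084, 0.091, 0.20 and 0.10), nor Gm4349 against KO YFP- (0.051). Without a filter on low values, Tox2, H2-DMa and Ado did not pass against WT YFP+ (0.11, 0.051 and 0.12), nor Ado against KO YFP- (0.072). The shared count was 13 without WT YFP+ 23, 11 without WT YFP+ 24, 14 without KO YFP+ 84, 8 without KO YFP+ 85 and 6 without SRC-3ff 72, and 3 with only the 4 libraries compared.

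WT YFP+ against SRC-3ff compared the 2 controls, which differ in strain and in the sort and not in the SRC-3 label. Cxcr6 (3.66 ± 0.0949 against 224 ± 100 FPKM), Lgals3 (1.31 ± 1.27 against 227 ± 100, log2 fold change -6.67 ± 0.43, limma adjusted p = 0.00070) and Itgae, which encodes the CD103 integrin chain (9.78 ± 1.36 against 55.0 ± 24.4), were lower in WT YFP+. Foxp1 (79.9 ± 2.41 against 19.9 ± 4.41), Ccr7 (450 ± 56.9 against 218 ± 37.9), Ifi206 (36.9 ± 2.60 against 3.44 ± 1.03), Dcaf13 (36.3 ± 2.38 against 5.15 ± 0.0264) and Atp5e (165 ± 3.70 against 33.2 ± 1.72, log2 fold change 2.27 ± 0.08, adjusted p = 0.00017) were higher. H2-Q4, a class Ib MHC gene, measured 89.2 ± 7.99 against 16.8 ± 2.29. All of these calls held with each library left out. Of 14134 genes, 1303 passed, 527 higher and 776 lower in WT YFP+ (705 and 648 with quantile normalization), with 172 segments, and 57.2% did not overlap (33.3% by chance). Of 101 named genes that passed, 47 held with each library left out. The count was 728 without WT YFP+ 23, 530 without WT YFP+ 24 and 400 without SRC-3ff 72, and 1076 without SRC-3ff 68. It was 717 without a filter on low values and 667 with only the 4 libraries compared.

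Between the controls, 15 of 25 effector Treg genes were lower in WT YFP+ (20 when adjusted over the list alone, median -1.30, camera adjusted p = 1.0e-11, adjusted p = 0.23 with an estimated correlation), among them S100a4 (30.9 ± 1.20 against 236 ± 92.2), a calcium-binding protein. Of 28 interferon response genes 6 rose (14 when adjusted over the list alone, median 0.79, camera adjusted p = 2.3e-09, adjusted p = 0.26 with an estimated correlation). Of 16 B cell markers 7 were lower (12 when adjusted over the list alone, camera adjusted p = 1.8e-09, adjusted p = 0.26 with an estimated correlation). Of 71 ribosomal protein genes 20 were higher (37 higher and 1 lower when adjusted over the list alone, median 0.43, camera adjusted p = 1.2e-14, adjusted p = 0.26 with an estimated correlation), a direction kept under both scalings. The immediate early list did not pass (2 higher and 3 lower, 3 and 3 when adjusted over the list alone, median -0.02, mean -0.09, with the test's direction up, adjusted p = 0.92). The Treg identity list did not pass either (2 higher and 3 lower, 4 and 4 when adjusted over the list alone), with a median of 0.09, a mean of -0.21, the test's direction up and an adjusted p of 0.92.

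**Figure D3:**
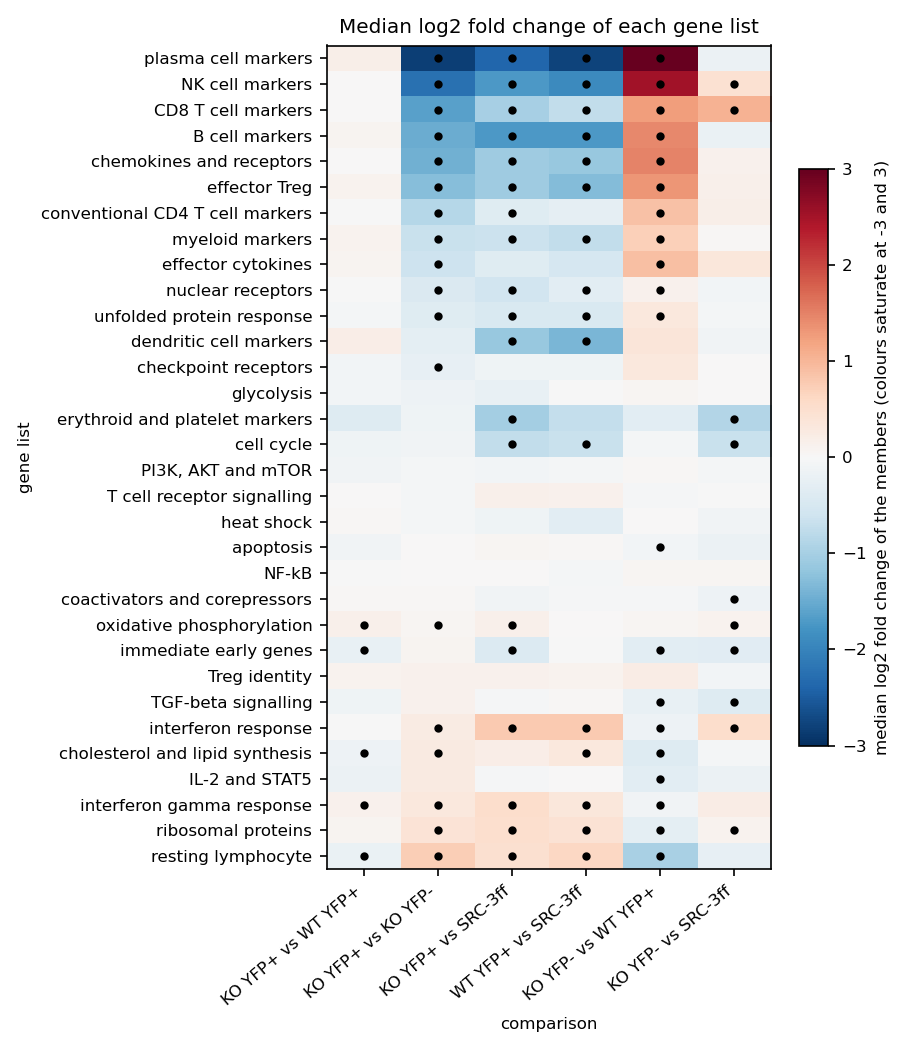
Median log2 fold change of the measured members of 32 gene lists (vertical axis) in 6 comparisons (horizontal axis), with colours that saturate at -3 and 3. Black dots mark camera adjusted p below 0.05 with the preset correlation, which 5, 18, 19, 16, 20 and 10 lists reached in the order plotted, and 0 lists reached with an estimated correlation.

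KO YFP- against WT YFP+ gave 1310 genes, 834 higher and 476 lower in KO YFP- (655 and 627 with quantile normalization), with 191 segments and 53.3% of genes not overlapping (33.3% by chance). Cxcr6 (355 ± 144 against 3.66 ± 0.0949 FPKM, log2 fold change 6.20 ± 0.37, limma adjusted p = 0.00090), Ccl5 (88.7 ± 0.301 against 2.43 ± 0.935), Tbx21 (59.1 ± 24.2 against 3.46 ± 1.24) and Tigit, a checkpoint receptor (58.6 ± 28.6 against 7.13 ± 2.30), were higher. S1pr1, the lymphocyte egress receptor (92.8 ± 11.2 against 212 ± 4.37), Il2ra (43.1 ± 0.497 against 113 ± 0.129) and Fos (35.9 ± 5.01 against 104 ± 10.7, -1.51 ± 0.13, adjusted p = 0.0016) were lower. These calls held with each library left out, and the Tigit call was lost without a filter on low values (adjusted p = 0.052). Of 25 effector Treg genes 19 rose and 1 fell (22 and 1 when adjusted over the list alone, median 1.31, camera adjusted p = 2.2e-13, adjusted p = 0.091 with an estimated correlation). Of 17 resting lymphocyte genes 2 rose and 10 fell (2 and 13 when adjusted over the list alone, median -0.98, camera adjusted p = 3.3e-08, adjusted p = 0.091 with an estimated correlation). Of 12 NK cell markers 11 were higher (11 when adjusted over the list alone, camera adjusted p = 4.9e-11, adjusted p = 0.091 with an estimated correlation). Of 26 immediate early genes 9 fell and 1 rose (12 and 1 when adjusted over the list alone, camera adjusted p = 2.1e-05, adjusted p = 0.099 with an estimated correlation). Of 91 named genes that passed, 50 held with each library left out. The count was 648 without WT YFP+ 23, 611 without WT YFP+ 24, 617 without KO YFP- 84 and 597 without KO YFP- 85, and 687 without a filter on low values and 803 with only the 4 libraries compared.

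KO YFP- against SRC-3ff compared the libraries labelled KO YFP- with the second control, 2 groups that were not sorted as YFP+ and did not differ in Ncoa3 past the threshold. Fos was lower in KO YFP- (35.9 ± 5.01 against 191 ± 16.9 FPKM, log2 fold change -2.38 ± 0.13, limma adjusted p = 0.0059), as were Jun, its AP-1 partner (100 ± 16.2 against 208 ± 14.7, adjusted p = 0.028), Il2ra (43.1 ± 0.497 against 95.0 ± 16.8, adjusted p = 0.026) and Gpr83 (29.7 ± 2.95 against 78.2 ± 12.6, adjusted p = 0.026). Cxcr3 was higher (197 ± 36.8 against 84.5 ± 4.42, adjusted p = 0.026), and so was Ccl5 (88.7 ± 0.301 against 24.2 ± 3.31, adjusted p = 0.030). In all 91 genes passed, 53 higher and 38 lower, with 7 segments, 2587 at an unadjusted p below 0.05 and 52.9% not overlapping (33.3% by chance). None of the 19 named genes that passed held with each library left out, and 0 genes passed without SRC-3ff 68, 11 without KO YFP- 85, 32 without KO YFP- 84 and 39 without SRC-3ff 72. The count was 0 with only the 4 libraries compared, 44 with a pseudocount of 0.1, 55 with a minimum of 5 FPKM and 39 with the animal number as a block. Fos did not pass without SRC-3ff 68 (adjusted p = 0.058), nor did Il2ra and Gpr83 without KO YFP- 84, KO YFP- 85 or SRC-3ff 68 (highest 0.099 for each). Jun and Cxcr3 did not pass without KO YFP- 85, SRC-3ff 68 or SRC-3ff 72 (highest 0.11 for each), nor Ccl5 without any 1 of KO YFP- 84, KO YFP- 85, SRC-3ff 68 and SRC-3ff 72 (highest 0.12). Il2ra and Ccl5 also did not pass with the animal number as a block (adjusted p = 0.050 for each), nor Ccl5 with a pseudocount of 0.1 (0.059). Without a filter on low values Jun, Il2ra, Gpr83, Cxcr3 and Ccl5 did not pass (0.060, 0.053, 0.056, 0.056 and 0.0725). Of 26 immediate early genes 5 fell (11 when adjusted over the list alone, median -0.34, camera adjusted p = 1.8e-05, adjusted p = 0.29 with an estimated correlation). Of 32 cell cycle genes 0 passed (1 lower when adjusted over the list alone, median -0.67, camera adjusted p = 5.2e-08, adjusted p = 0.58 with an estimated correlation). Of 28 interferon response genes 0 passed (6 higher in KO YFP- when adjusted over the list alone, median 0.54, camera adjusted p = 5.3e-06, adjusted p = 0.58 with an estimated correlation). The median of this list was thus above 0 against SRC-3ff in KO YFP- as in both YFP+ groups. Some lists of markers of other cell types also passed with camera between these 2 groups, but not with an estimated correlation. Of 9 CD8 T cell markers, among them Ccl5, 1 was higher in KO YFP- (6 when adjusted over the list alone, median 1.05, camera adjusted p = 6.7e-05, adjusted p = 0.29 with an estimated correlation). Of 12 NK cell markers 0 passed (4 higher and 1 lower when adjusted over the list alone, median 0.47, camera adjusted p = 0.014, adjusted p = 0.58 with an estimated correlation). Of 7 erythroid and platelet markers 0 passed (2 lower when adjusted over the list alone, median -0.87, camera adjusted p = 0.0010, adjusted p = 0.58 with an estimated correlation). The NK cell list did not pass without SRC-3ff 68 (adjusted p = 0.17), nor the erythroid and platelet list without SRC-3ff 72 (0.084).

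Sex-linked and strain genes were read in every library. Xist, the X inactivation transcript, measured 1.49 to 3.87 FPKM, and the Y-linked genes Ddx3y, Kdm5d and Eif2s3y were listed at 0 in all 8 libraries, with Uty at most 0.0195. Xist was higher in KO YFP- than in WT YFP+ (log2 fold change 0.77, limma adjusted p = 0.036), but not without any 1 of these 4 libraries (adjusted p of 0.085 to 0.17), without a filter on low values (0.078), with quantile normalization (0.086), with only the 4 libraries compared (0.11) or with the animal number as a block (0.051). Nnt, a nicotinamide nucleotide transhydrogenase that carries a deletion in some C57BL/6 substrains, measured 16.8 ± 0.211 in WT YFP+, 19.6 ± 2.39 in KO YFP+, 20.4 ± 0.467 in KO YFP- and 24.8 ± 0.545 in SRC-3ff (SD, n = 2 each). It differed between WT YFP+ and SRC-3ff (log2 fold change -0.53, limma adjusted p = 0.031), but not without any 1 of WT YFP+ 23, WT YFP+ 24, SRC-3ff 68 and SRC-3ff 72 (adjusted p of 0.085 to 0.17), without a filter on low values (0.057) or with only the 4 libraries compared (0.066). Gbp2b, an interferon-induced GTPase, measured 13.8 ± 5.35, 29.4 ± 0.793, 11.6 ± 0.114 and 25.3 ± 2.41 in the same order. It was higher in KO YFP+ than in KO YFP- of the same animals (log2 fold change 1.26, adjusted p = 0.029), but not without any 1 of these 4 libraries (adjusted p of 0.11 to 0.15), without a filter on low values (0.12) or with the animal number as a block (0.052). Entpd4, Wdfy1 and Gbp2b did not pass in KO YFP+ against WT YFP+, and Ifi202b was below 1 FPKM in every library.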

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

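Leaving out antigen receptor segments was chosen after seeing the data. All other alternatives were fixed beforehand. The cause of a moved count was not tested, except that fewer libraries (without 1, or only 4) leave fewer residual degrees of freedom. Without a filter on low values the counts were 68 (KO YFP+ vs WT YFP+), 226 (KO YFP+ vs KO YFP-), 567 (KO YFP+ vs SRC-3ff), 717 (WT YFP+ vs SRC-3ff) and 687 (KO YFP- vs WT YFP+), against 107, 693, 1448, 1303 and 1310. With only the 4 libraries compared they were 25 (KO YFP+ vs WT YFP+), 537 (KO YFP+ vs SRC-3ff), 667 (WT YFP+ vs SRC-3ff), 803 (KO YFP- vs WT YFP+) and 0 (KO YFP- vs SRC-3ff), and the count of genes shared against both controls was 3, against 19. KO YFP- vs SRC-3ff gave 44 with a pseudocount of 0.1 and 55 with a minimum of 5 FPKM, against 91. With a library left out, counts ranged from 44 to 74 (KO YFP+ vs WT YFP+), 140 to 345 (KO YFP+ vs KO YFP-), 215 to 1061 (KO YFP+ vs SRC-3ff), 400 to 1076 (WT YFP+ vs SRC-3ff), 597 to 648 (KO YFP- vs WT YFP+), 0 to 39 (KO YFP- vs SRC-3ff) and 6 to 19 (shared genes).

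With the animal number as a block, pairing the knockout sorts, KO YFP- vs SRC-3ff gave 39 calls, and the other 5 counts were 90, 557, 1236, 1235 and 1174. The block ended the gene calls stated so in the report and those of Sdc4 and Prex1 in KO YFP+ vs WT YFP+ (adjusted p = 0.064 and 0.083). Genes higher in KO YFP+ than in KO YFP- numbered 132 with it, against 204. With an estimated correlation 0 lists passed with camera in each comparison, and 1, 9, 4, 5, 9 and 2 had an unadjusted p below 0.05. Over 519 pairs of a named gene and a comparison, 4059 results with other settings stayed on their side of the threshold and 534 were lost, and with a library left out 1167 stayed, 906 were lost and 3 changed sign. These were Foxp3 (0.14 without WT YFP+ 23, range -0.48 to 0.14) and Ifng (0.023 without KO YFP+ 85, range -0.077 to 0.023) in KO YFP+ vs WT YFP+, and Ncoa3 in WT YFP+ vs SRC-3ff (-0.16 without SRC-3ff 72, range -0.16 to 0.32), none past the threshold. Depth is unknown, so no counting error was set against these values.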

Other observations

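The tests of explanations were chosen only after the results were seen. The genes Trgc1, Trgc2, Trdc, Trav11, Zbtb16, Sdc4, Prex1 and Serinc3 were also chosen after their values were seen, and no list of the first 5 was tested. Trgc1 and Trgc2, constant segments of the T cell receptor gamma chain, measured 2.18 and 2.42, and 0.729 and 1.13 FPKM in WT YFP+ 23 and 24, and 1.01 and 3.44, and 1.32 and 1.86 in KO YFP+ 84 and 85. They measured 78.1 and 156, and 92.9 and 166 in KO YFP- 84 and 85, and 87.5 and 198, and 68.2 and 136 in SRC-3ff 68 and 72. Trdc, the delta constant segment, differed between KO YFP+ and KO YFP- by a log2 fold change of -3.63 (limma adjusted p = 0.0055), Trgc2 by -5.60 (adjusted p = 0.0024) and Trav11, the variable segment of invariant NKT cells, by -4.62 (adjusted p = 0.0038), all held with each library left out. The Trdc call was lost without a filter on low values (adjusted p = 0.055). Zbtb16, the transcription factor PLZF of innate-like T cells, measured 0.0309 in WT YFP+ 23 and was listed at 0 in WT YFP+ 24. It measured 0.0981 and 0.0212 in KO YFP+ 84 and 85, 5.60 and 18.0 in KO YFP- 84 and 85, and 5.11 and 8.35 in SRC-3ff 68 and 72.

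The difference between KO YFP+ and WT YFP+ may come largely from strain or from another trait of the WT YFP+ libraries, which cannot be told apart. For 91 of 107 genes the mean of KO YFP- and SRC-3ff lay nearer KO YFP+ (51.0% over all tested genes). Of the 74 genes called without WT YFP+ 23, 58 lay so when set against that library alone (54.0% over all genes), as did 52 of the 64 called without WT YFP+ 24 (56.5%). Without antigen receptor segments, 62 of 78 called genes lay nearer KO YFP+. KO YFP-, a part of that mean, carries the animal numbers of KO YFP+. SRC-3ff does not, and 84 of the 107 genes also differed between WT YFP+ and SRC-3ff, with SRC-3ff on the side of KO YFP+. Loss of SRC-3 as the cause of the whole pattern is argued against by 92 of the 107 genes. These also differed, in the same direction, between WT YFP+ and the mean of KO YFP- and SRC-3ff. At most 9 did so in 100 simulations in which the called genes differed in KO YFP+ alone. The simulations held no difference between the sorts in those genes. KO YFP- and SRC-3ff were not sorted as YFP+, so a part of the 92 from the sort was not weighed. Of the 16 genes nearer WT YFP+, 9 also differed between the sorts of the same animals, among them Ncoa3 itself, Zmiz1 and Tox2. Apart from Ncoa3, loss of SRC-3 cannot be told apart in these 9 from a strain difference seen in YFP+ cells alone. The reason is that no YFP+ control shares the knockout's strain. The rest of the 16 did not pass between the sorts in that direction, so a difference tied to Ncoa3 was not shown for them. Fos was 1 of these (log2 fold change -0.07, limma adjusted p = 0.85). Genes within 20 Mb of Ncoa3 were enriched, 9 of 289 against 0.757% of all genes (odds ratio 4.55, Fisher's exact test, two-sided, p = 0.00032), but donor DNA kept around the targeted locus cannot be told apart from other causes, since Tox2, Sdc4 and Prex1 lay nearer WT YFP+, as it would not give, and of the 9 calls only those of Atp5e and Serinc3 held with each library left out (highest adjusted p = 0.17, 0.20 and 0.24 for Tox2, Sdc4 and Prex1).

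Foxp3 was lower in both YFP+ groups. A fall in the share of Tregs among YFP+ cells as large as that of Foxp3 is argued against by the 18 other Treg identity genes. Their median log2 difference between KO YFP+ and KO YFP- was 0.127 (quartiles -0.19 and 0.94). The share itself was not measured, and KO YFP- also held markers of other lymphocytes, so a smaller difference in share is left open. Loss of SRC-3 is argued against by WT YFP+, which lay below SRC-3ff by a log2 fold change of -2.78. If YFP is carried by an allele of Foxp3, which the labels do not say, reads of it missed in quantification may account for the -2.56 between KO YFP+ and KO YFP-. So may a lower transcript level from that allele. These parts cannot be told apart from 1 value per gene.

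Markers of other lymphocytes were higher where cells were not sorted as YFP+, and Igkc, the immunoglobulin kappa constant segment of B and plasma cells, measured 4704 and 2556 FPKM in KO YFP- 84 and 85 against 262 and 338 in KO YFP+ 84 and 85. Of 50 measured B, plasma, NK and myeloid markers, 48 (96%) had a lower fitted value in KO YFP+ than in KO YFP-, past the threshold or not. The median was -1.68, against -0.024 over all tested genes. Those past the threshold were 5 B, 3 plasma, 10 NK and 3 myeloid markers. Markers near 0 in YFP+ cells passed the filter on low values only through other libraries, which largely fixed their direction. The markers also define the pattern, so the share is no separate test of its cause. Cells of other lineages in the KO YFP- libraries may be part of it, although the labels name these cells Tregs. Other lists also hold Eomes, Gzmb, Klrd1, Nkg7, Prdm1, Tbx21 and Xbp1. More effector-like Tregs outside the YFP+ sort may also contribute. Effector Treg genes held by no NK cell, CD8 T cell, B cell, plasma cell or conventional CD4 T cell list numbered 22. Of these, 21 (95.5%) had a lower fitted value in KO YFP+ than in KO YFP-. This counts genes past the threshold or not, and of all 25 measured in the list 14 passed as lower. Effector-like Tregs cannot be told apart here from other activated T cells, which express the same genes.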
